A study of Homo sapiens with 6 samples.

How the data were processed

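The series profiled RNA from H1048 cells, a human small cell lung cancer line, in 6 samples: 3 samples exposed to ISP-I (isovalerylspiramycin I, a macrolide antibiotic component) at 10 µM and 3 exposed to the solvent DMSO, each for 48 h. The series' design text calls the samples of a group biological replicates. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with a NEBNext Ultra RNA kit and sequenced as paired ends on a NovaSeq instrument. The submitters' processing notes name Trimmomatic, STAR, HTSeq, DESeq2 and the build hg38; versions, parameters, the gene annotation and the use of strand are not given in the sources used here.

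The processed data were 2 tables of the authors' own comparison, which sets libraries D, E and F against libraries A, B and C. For each gene the authors deposited a log2 fold change, a p-value and an adjusted p-value, under the column names that DESeq2 gives them, per the file headers; whether the fold changes were shrunken is not given in the sources used here. A positive log2 fold change is read as higher in libraries D to F, from the order in which the authors' table names the sets. The smaller table held 4021 genes and was tested to be exactly the part of the larger one with an unadjusted p under 0.05 and an absolute log2 fold change of at least 1, with identical values for all 4021; its marks of up and down followed the sign of the fold change in all of them.

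No label ties a library letter to a sample title or to a treatment. The sources used here therefore do not state which set was treated with ISP-I, and the direction of the comparison is given only as D to F relative to A to C. Because no label shows which sample each column holds, the 36 columns of values per library (18 in each table) were not used for any result (their ranges and totals, and the sign of their difference against the authors' fold change, were looked at while the units were checked, and the values of 2 genes were displayed in a later check of rounding), so depth per library, means, standard deviations and a count model of the replicates are not given, and the count-based test fixed before the data were examined was replaced by the authors' deposited p-values. These tables give no standard errors, and none were derived.

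The larger table held 16953 genes, of which 16922 were protein-coding by a match of symbols to GENCODE release 29 (GRCh38); 16928 symbols matched 1 gene there. In the authors' table, 977 genes had an adjusted p of exactly 1, and the other adjusted values correspond to a Benjamini-Hochberg adjustment over 15976 tests, the number of the remaining genes. The 977 genes were treated as having no adjusted p. For 10 genes the authors' p-value is listed at 0, below the smallest value the table holds otherwise (1.46e-295). A gene was called higher or lower at an adjusted p under 0.05.

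A set of 33 gene lists was fixed before the data were examined: stress, damage, cell cycle, metabolic, signalling and lineage lists, and markers of fibroblasts, leukocytes and endothelium. Of 737 listed members 710 had a value; the other 27 were not analysed here. Lists were tested with cameraPR (limma 3.58.1, R 4.3.3), which compares the members of a list with all other genes, on signed z values computed from the authors' p-values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 33 lists. This test replaced a planned camera test on counts per library and was chosen after the authors' fold changes, those of the lists included, had been looked at. A correlation was not estimated, since that takes the values per library that were left out, and 0.05 was run as a second preset value. On shuffled z values, 3 of 100 runs gave any false call. Lists shifted by 1, 3 and 6 z units (the z values had a standard deviation of 5.72) were recovered in 0, 23 and 96 of 100 cases. Shuffling removes correlation between the members of a list. These rates therefore do not show how often correlated lists are falsely called.

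Named genes followed a rule fixed before the data were examined: the 12 largest changes in each direction at an adjusted p under 0.05 with a gene symbol, up to 4 members of each list with the smallest p, and 17 genes always named; some genes that the rule takes are not reported here. The rule's minimum of 50 normalized counts and its demand that all libraries of one set lie above all of the other were not applied, since both take values per library, so the largest fold changes include genes whose counts may be low; the 10 genes with the smallest p in each direction were added after their values were seen, as were list members beyond these. Coordinates are those of GENCODE 29 on GRCh38, 1-based. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.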

Results

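RNA was sequenced from 6 samples of H1048, a small cell lung cancer line of the POU2F3 (tuft cell-like) subtype, 3 exposed to the macrolide ISP-I at 10 µM and 3 to DMSO for 48 h. The title of the series names DNA damage through reactive oxygen species and stress of the endoplasmic reticulum, and the comparison addresses which genes differ between the treatments. The authors' deposited table compares 2 sets of 3 libraries, D to F against A to C, without naming the treatment of either set in the sources used here. All values below are therefore differences of D to F relative to A to C as the authors computed them, with their adjusted p and without standard errors.

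Growth and stress signalling genes such as EGR1 (378.4-fold), the heme oxygenase HMOX1 (344-fold), GADD45A (19.5-fold) and DDIT3 (9.81-fold) were higher in libraries D to F. The tuft cell factor POU2F3 (3.28-fold), the desaturase SCD (5.46-fold) and the collagen COL15A1 (23.3-fold) were lower, all as listed in the authors' deposited table. Most of the tested genes differed between the sets. In the authors' deposited table, 4742 of 15976 genes with an adjusted p (29.68%) were higher in libraries D to F and 4453 (27.87%) were lower at an adjusted p under 0.05. At least 2-fold, 2052 genes were higher and 1804 lower, or 1901 and 1953 with fold changes centred on the median of all genes. Large increases outnumbered large decreases, with 295 genes at least 16-fold higher and 38 at least 16-fold lower. The median log2 fold change over all 16953 genes was 0.06, and that of called genes was 0.86 in absolute size.

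**Figure D1:**
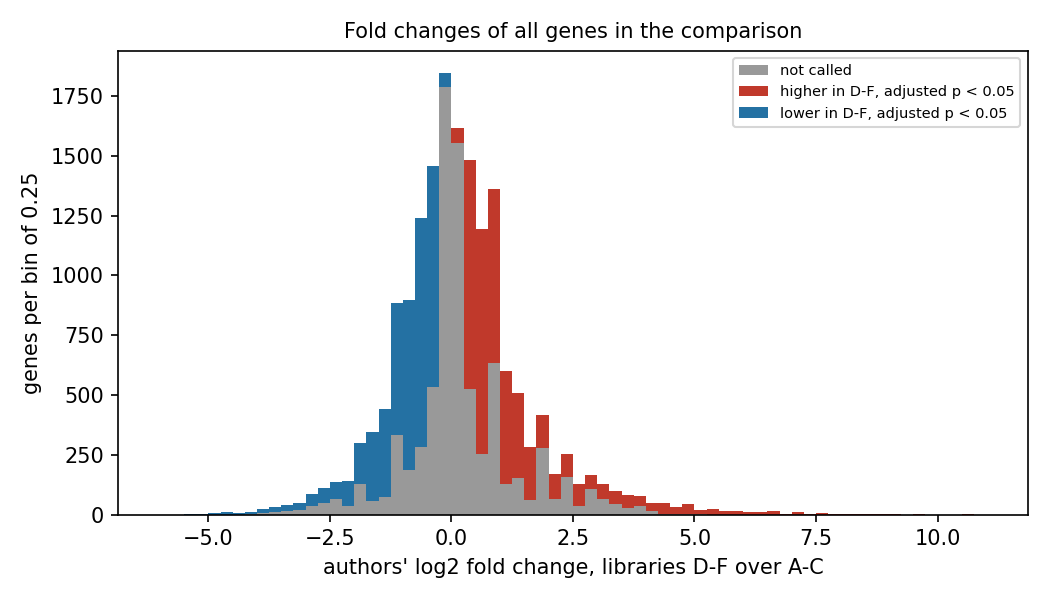
Histogram of the authors' log2 fold change (x axis, libraries D to F over A to C) for 16953 genes, in bins of 0.25 (y axis, genes per bin), coloured by whether the gene was higher, lower or not called at an adjusted p under 0.05. The right tail extends to VGF at 10.62, the left tail to KRT1 at -5.46 among called genes.

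The largest increases in libraries D to F were of VGF, a secreted neuropeptide precursor (chromosome 7, 101162509 to 101165593; log2 fold change 10.62, adjusted p = 3.28e-162 in the authors' deposited table), the potassium channel KCNMA1 (9.74, adjusted p = 3.41e-15) and C11orf96 (9.04). They were followed by the pregnancy-specific glycoprotein PSG8 (8.89), the transcription factor EGR2 (8.82), EGR1 (chromosome 5, 138465490 to 138469315; 8.56, adjusted p listed at 0) and the heme oxygenase HMOX1 (chromosome 22, 35380361 to 35394214; 8.43, adjusted p listed at 0). ARC (8.27), BHLHE41 (8.26), INSL4 (8.13) and the receptor tyrosine kinase AXL (8.06) came next. PSG8 belongs to a family of near-identical genes between which reads may be split, so its own value is uncertain.

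The largest decreases were of KRT1 (log2 fold change -5.46, adjusted p = 0.0012 in the authors' deposited table), CABS1 (-5.42), PLAC1 (-5.10), BLNK (-5.09) and the mechanosensitive channel PIEZO2 (-5.05, adjusted p = 3.14e-13). TIGIT (-4.98), the cadherin CDH22 (-4.97, adjusted p = 1.81e-179), AMBN (-4.96), ABI3 (-4.88), sucrase-isomaltase SI (-4.84), SPINK7 (-4.79) and ANKRD22 (-4.72) followed. Most of these had adjusted p-values many orders of magnitude above those of CDH22 at a similar fold.

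Ranked by p instead, a choice made after the values were seen, the genes higher in D to F were led by the stress and growth arrest gene GADD45A (19.5-fold; chromosome 1, 67685061 to 67688338), EGR1, HMOX1, the cytochrome CYP1A1 (31.5-fold), KLF6 (13.6-fold), PPP1R15A (11.7-fold), JUN (log2 fold change 4.17), the intestinal transcription factor CDX2 (18.3-fold), TNFRSF12A (45.5-fold) and KLF10 (11.6-fold), the first 9 with a p listed at 0 in the authors' deposited table. The genes lower were led by the collagens COL15A1 (23.3-fold lower; chromosome 9, 98943179 to 99070792) and COL2A1 (5.65-fold lower), NREP (12.6-fold lower), DPYSL3 (5.85-fold lower), STC1 (6.92-fold lower), CDH22 (31.4-fold lower), PIK3C2B (6.41-fold lower), the cytoplasmic actin ACTB (4.90-fold lower), the stearoyl-CoA desaturase SCD (5.46-fold lower) and LGALS3BP (5.79-fold lower).

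Of the 33 gene lists, 10 differed from the other genes at an adjusted p under 0.05 (cameraPR), 6 of them toward higher and 4 toward lower values in libraries D to F. Adjusted over the list alone instead of over all genes tested, no list's count of members higher or lower moved by more than 1; counts below are over all genes tested, and the other count is given where it differs. With the preset correlation raised to 0.05, 9 of the 10 lists remained past the threshold; 3 passed in the same direction under all 4 other ways of running the test, namely the immediate early, oxidative stress and NF-kB lists.

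**Figure D2:**
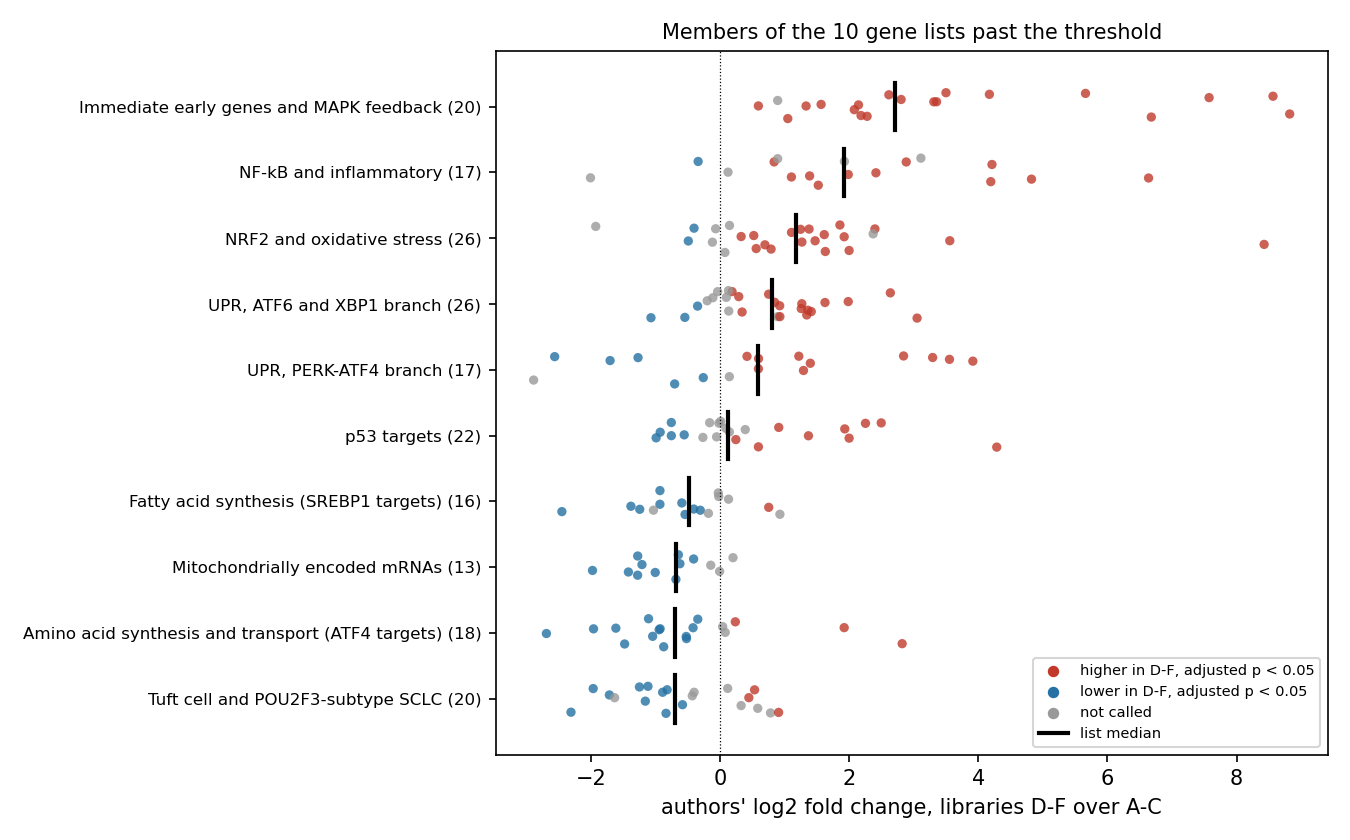
Authors' log2 fold change (x axis, libraries D to F over A to C) of each measured member of the 10 gene lists past the threshold (y axis, number of members in brackets); each point is a gene, coloured by its call at an adjusted p under 0.05, and the black bar is the list's median. List medians run from 2.71 for immediate early genes to -0.70 for tuft cell genes.

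Immediate early genes, which are transcribed within minutes of growth factor or stress signals, were higher together with the phosphatases and adaptors that feed back on MAP kinase signalling. In this list 19 of 20 measured members were higher in libraries D to F and none lower, 19 also when adjusted over the list alone, with a median log2 fold change of 2.71 (cameraPR adjusted p = 2.94e-41). EGR1 (8.56), JUN (4.17), IER2 (3.35) and PHLDA1 (3.50) had the smallest p-values, and FOS was at 7.57 and FOSL1 at 5.66. Among the feedback regulators, DUSP6 was at 2.15 and SPRY4 at 2.18. The remaining member, IER3, had no adjusted p. Its listed fold change is the same to 3 decimals in 377 genes, IER3 included, of which none was called, and carries no information on IER3 itself. Members of other lists that are counted as measured share this value and also lack an adjusted p, among them HYOU1, CXCL1 and RPL7A. IER3 lies in a region of chromosome 6 where few genes carried an adjusted p.

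NF-kB and inflammatory genes were higher in 11 of 17 members and lower in 1 (11 and 1 also adjusted over the list alone; median 1.93, cameraPR adjusted p = 2.18e-05). They included the subunits NFKB1 (1.52) and RELB (1.99), the feedback inhibitor TNFAIP3 (2.42), and the secreted factors CXCL8 (6.64), LIF (4.19) and IL6 (4.82). The mitochondrial superoxide dismutase SOD2 was the member lower (-0.34).

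Oxidative stress genes of the NRF2 programme were higher in 18 of 26 members and lower in 2, the same numbers when adjusted over the list alone (median 1.18, cameraPR adjusted p = 2.31e-11). HMOX1 was 344-fold higher, OSGIN1 had a log2 fold change of 3.56, the ferritin chain FTL 2.40 and the thioredoxin reductase TXNRD1 1.86 in the authors' deposited table. The cystine transporter SLC7A11 (1.92), the glutathione synthesis subunits GCLC (1.38) and GCLM (1.62), and NQO1 (1.47) were also higher, while the pentose phosphate enzymes PGD (-0.40) and TALDO1 (-0.49) were lower. A separate list of antioxidant enzymes had 2 members higher and 12 lower of 19 (13 lower adjusted over the list alone) and a median of -0.32, with GPX8 at -1.86, the mitochondrial peroxiredoxin PRDX3 at -1.23, TXN2 at -0.47 and TXNRD2 at 0.68; it did not pass (cameraPR adjusted p = 0.105).

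The unfolded protein response was represented by separate lists, both higher in libraries D to F. In the PERK-ATF4 list 10 of 17 members were higher and 5 lower, also adjusted over the list alone (median 0.60, cameraPR adjusted p = 1.55e-05). PPP1R15A (3.55), GDF15 (3.92), ATF3 (2.84) and DDIT3, which encodes CHOP (9.81-fold), were higher, and ATF4 itself was 2.64-fold higher. DDIT4 (-2.56), VLDLR (-1.70), CTH (-1.27) and CHAC1 (-0.70) were lower. In the list of ER chaperones and degradation genes controlled by ATF6 and XBP1, 16 of 26 members were higher and 3 lower, or 4 adjusted over the list alone (median 0.80, cameraPR adjusted p = 3.62e-05). XBP1 was 6.23-fold higher, DNAJB9 had a log2 fold change of 3.05, SELENOS 1.99, DERL2 1.41 and DNAJC3 1.27, and the chaperone HSPA5 (BiP) was 1.90-fold higher, whereas PDIA4 was at -1.07 and CALR at -0.54. The PERK-ATF4 call ended when ranks (adjusted p = 0.099) or fold changes (adjusted p = 0.493) replaced z, and the ATF6 and XBP1 call ended with fold changes (adjusted p = 0.192).

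Amino acid synthesis and transport genes, which ATF4 can induce, went the other way. In this list 13 of 18 members were lower and 3 higher, the same numbers adjusted over the list alone (median -0.70, cameraPR adjusted p = 0.0451). The serine synthesis enzymes PHGDH (-1.61), PSAT1 (-1.48) and PSPH (-1.96) were lower, as was the glycine transporter SLC6A9 (-2.69). The subunits of the cystine exchanger, SLC3A2 (2.82) and SLC7A11 (1.92), were among the 3 members higher. The call ended at a preset correlation of 0.05 (adjusted p = 0.165), with fold changes in place of z (0.169) and over genes with an adjusted p only (0.0548). Cytosolic tRNA synthetases were divided, 6 higher and 6 lower of 17, with 7 higher adjusted over the list alone (cameraPR adjusted p = 0.829); QARS (-0.95) and MARS (-0.66) were lower, and WARS (0.81) and DARS (0.66) higher.

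Targets of p53 were higher in 9 of 22 members and lower in 5, or 6 adjusted over the list alone (median 0.12, cameraPR adjusted p = 0.000804). The members with the smallest p were GADD45A (4.29), the cell cycle inhibitor CDKN1A (5.65-fold higher), PMAIP1, which encodes NOXA (2.25), and AEN (1.93); FAS (-0.75) and TP53INP1 (-0.99) were lower. The list's call ended with ranks (adjusted p = 0.353) or fold changes (adjusted p = 0.483) in place of z.

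No other list of DNA damage or cell division passed the test. Checkpoint and damage signalling genes were 7 higher and 9 lower of 23 (cameraPR adjusted p = 0.982), with CHEK1 at 0.89, ATR at 0.77, CDC25A at 0.95 and TIMELESS at -1.89; H2AX, listed as H2AFX, was slightly lower (log2 fold change -0.31, adjusted p = 0.000563 in the authors' deposited table). Homologous recombination and Fanconi genes were 8 higher and 8 lower of 27 (adjusted p = 0.967), with RPA2 at 1.01, RAD51C at 1.05, RPA1 at -0.88 and FANCD2 at -0.83. Base excision, mismatch and end-joining repair genes were 7 higher and 6 lower of 22 (adjusted p = 0.731; 8 higher adjusted over the list alone), with PARP1 at -1.47, LIG3 at -1.05, APEX1 at -0.79 and LIG4 at 0.77. Replication and G1/S genes were 16 higher and 7 lower of 36 (adjusted p = 0.0804; 8 lower adjusted over the list alone), led by the licensing factors CDT1 (1.83) and CDC6 (1.15), with RFC2 at 0.89 and MCM5 at 0.74. Mitotic genes were 10 higher and 11 lower of 34 (adjusted p = 0.829), with HMMR at 0.80, FOXM1 at -0.76, CENPF at -0.88, NUF2 at -0.94 and MKI67 at -0.91. Replication-dependent histones were 3 higher and 1 lower of 13, with HIST1H4C at 5.87, HIST1H1E at 3.54, HIST1H1C at 1.17 and HIST2H2BE at -0.79 (adjusted p = 0.581; 0 lower adjusted over the list alone). Apoptosis regulators were 11 higher and 7 lower of 26 (adjusted p = 0.291; 8 lower adjusted over the list alone); MCL1 (1.73), HRK (3.06) and BAK1 (1.21) were higher, and BCL2 (-1.01) and APAF1 (-1.63) lower.

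All called transcripts of the mitochondrial genome were lower. Of 13 mitochondrially encoded mRNAs, 10 were lower and none higher, also adjusted over the list alone (median -0.68, cameraPR adjusted p = 2.46e-06), among them MT-ND6 (-1.97), MT-ND5 (-1.42), MT-CO1 (-1.27) and MT-CO2 (-1.28). Nuclear genes of oxidative phosphorylation were 14 lower and 2 higher of 33, including COX6C (-1.26), SDHC (-0.58) and ATP5F1B (-0.54), without passing (adjusted p = 0.193). Mitochondrial ribosomal proteins were 15 higher and 2 lower of 28, including MRPS2 (1.38), MRPL17 (1.01), MRPS30 (0.80) and MRPS10 (0.79), also without passing (adjusted p = 0.0766). Cytosolic ribosomal proteins were 12 higher and 7 lower of 40 (adjusted p = 0.692; 11 higher adjusted over the list alone), with RPL18 at 0.76, RPL10A at 0.61, RPS15 at 0.41 and RPL3 at -0.67. The mitochondrial mRNA call ended with fold changes in place of z (adjusted p = 0.0946).

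Of 16 fatty acid synthesis genes 9 were lower and 1 higher, also adjusted over the list alone (median -0.47, cameraPR adjusted p = 0.00229), led by SCD (-2.45), ACLY (-1.38), FADS2 (-1.24) and ACSL1 (-0.93), with the lipin LPIN1 (0.76) higher. Cholesterol synthesis genes were 15 lower and 5 higher of 25, including SQLE (-1.15) and LSS (-1.11), but the list did not pass (adjusted p = 0.0766). The fatty acid call ended with fold changes in place of z (adjusted p = 0.18).

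Lysosome and autophagy genes were divided, 10 higher and 12 lower of 30 (adjusted p = 0.13). The autophagy receptor SQSTM1 (2.89) and GPNMB (4.48) were higher, and the lysosomal hydrolases and membrane proteins CTSA (-2.24), LIPA (-2.31), LAMP1 (-1.73) and PSAP (-1.43) were lower. Selenoproteins and their machinery were also divided, 10 higher and 9 lower of 23 (adjusted p = 0.198; 11 higher adjusted over the list alone). The ER-membrane selenoproteins SELENOS (1.99) and SELENOK (2.73-fold), TXNRD1 (1.86) and SELENOI (1.26) were higher, and SELENON (-1.82) and SEPHS1 (-1.17) lower. Glycolysis and hypoxia genes were 10 higher and 9 lower of 28 (adjusted p = 0.829; 11 higher adjusted over the list alone), with the peptide hormone gene ADM at 3.75, SLC2A1 at 1.48, PGK1 at -1.07 and GPI at -1.23. Cytosolic chaperones were 3 higher and 3 lower of 13 (adjusted p = 0.829), with HSPA8 at -0.85, HSP90AA1 at -0.54, HSPA4 at 0.54 and BAG3 at 0.68. Of the 16 genes in the chaperone list only these 13 had a value. The heat shock genes HSPA1A and HSPA1B were not among them, so the result does not speak to those genes. Interferon response genes were 4 higher and 9 lower of 20 (adjusted p = 0.345), with STAT2 at -1.19, OAS3 at -0.71, IFIT3 at -2.41, HERC5 at 1.00 and OAS2 at 4.72, and DDX58 also lower.

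POU2F3, the factor that defines the tuft cell-like subtype, was 3.28-fold lower in libraries D to F (chromosome 11, 120236640 to 120319944; adjusted p = 3.42e-89 in the authors' deposited table). Of 20 tuft cell genes 10 were lower and 3 higher, also adjusted over the list alone (median -0.70, cameraPR adjusted p = 0.00142), including AVIL (-2.31), the receptor KIT (-1.96) and SOX9 (-1.25). The call ended with ranks (adjusted p = 0.0703) or fold changes (adjusted p = 0.119) in place of z. Neuroendocrine genes were 6 higher and 3 lower of 13 and did not pass (adjusted p = 0.206). SYP (2.51), INSM1 (1.81), BEX1 (1.64) and CHGB (4.38) were higher and NCAM1 (-0.80) lower. NEUROD1 was among the genes treated here as having no adjusted p. MYC was 1.63-fold higher, MYCL 5.37-fold lower and YAP1 1.28-fold higher.

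Epithelial and mesenchymal genes were 12 higher and 3 lower of 18 (median 0.60, cameraPR adjusted p = 0.0505), with the keratins KRT8 (1.24) and KRT18 (1.12), CYR61 (1.91) and the factors SNAI1 (2.76) and ZEB1 (3.37) higher, and FN1 (-2.07) and CDH1 (-1.34) lower. Among markers of other cell types, fibroblast genes were 6 lower and 1 higher of 11 (median -1.86, adjusted p = 0.33), with POSTN at -3.97, PDGFRA at -1.91, COL1A1 at -0.57 and FAP at 3.82. Leukocyte genes were 1 higher and none lower of 9 (adjusted p = 0.829), the call being LYZ at 4.90 while CSF1R (2.02) and CD14 (0.83) were not called, and endothelial genes were 1 higher and 1 lower of 7 (adjusted p = 0.943), namely ESAM (0.94) and EGFL7 (-1.35), with CLDN5 (1.52) and TEK (-3.67) not called.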

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

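No paired analysis was possible because the values per library were not tied by any label to the samples and their replicate numbers. Columns without a labelled sample were left out by choice, although their letters name the compared sets, so settings that use them (other tools, normalizations, count filters, the estimated correlation, fry, and leaving out each replicate) were not run. An unadjusted p under 0.05, set before the data were examined, gave 5032 genes higher and 4724 lower; all other settings run were chosen after seeing the data. The counts of genes stayed within 1.5 times their value under an unadjusted p, an adjustment over all 16953 genes, an adjusted p under 0.01, protein-coding genes alone and, for the 2-fold counts, centring on the median of all genes. Of these settings, protein-coding genes alone (16922 of 16953) and the adjustment over all genes (16953 in place of 15976 tests) could hardly move the counts. Centred, 1901 genes were at least 2-fold higher and 1953 lower, so which direction held more of these genes depended on it (2052 and 1804 as deposited). Centring changed the sign of none of the called genes, but it subtracts only 0.06 and could hardly have done so. The number of gene lists past the threshold was 10, and 4 when fold changes replaced z; the cause was not tested. By list, 7 calls were lost and 1, of fibroblast markers, was gained with fold changes. With ranks, 3 were lost and 4 gained, namely antioxidant enzymes, cholesterol synthesis, the mitochondrial ribosome and the mixed list of epithelial and mesenchymal genes. Median and test differed in sign for the homologous recombination, base excision, cytosolic chaperone and endothelial lists, none of which passed. Both fold change and p were shared exactly with another gene by 1602 genes in the authors' deposited values, 12 of them called. The depth behind each value is unknown here.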

Other observations

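All tests in this part were chosen after the table of fold changes had been seen. For the family screen and the comparisons of the immediate early list, the values they measure had been seen too. A screen of 277 gene families, formed from the shared start of their symbols and holding at least 8 members with an adjusted p, found 13 past an adjusted p of 0.05 (cameraPR). A higher preset correlation, ranks or fold changes in place of z, each of which ended some list calls, were not run for the families. How many of the 13 would remain under them is therefore unknown. Higher in libraries D to F were all 11 UTP genes of the small subunit processome (median log2 fold change 1.01, adjusted p = 0.00126), including UTP23 (1.67) and UTP4 (1.61), and all 8 RRP genes (median 1.00, adjusted p = 0.00152), including RRP9 (2.15) and RRP12 (1.43). The nucleolar and RNA processing stems NOL and EXOSC did not pass, with NOL 5 higher and 4 lower of 10 (adjusted p = 0.761) and EXOSC 7 higher and 0 lower of 10 (adjusted p = 0.102). Genes with the EIF stem, grouped by symbol and not restricted to translation initiation factors, were 27 higher and 6 lower of 48 (adjusted p = 0.00200). Krüppel-like transcription factors were 10 higher and 2 lower of 16 (median 1.17, adjusted p = 1.63e-05), with KLF6 (3.77) and KLF10 (3.54) the smallest in p, and DUSP phosphatases 12 higher and 3 lower of 21 (adjusted p = 0.00126). The IRF stem was 6 higher and 0 lower of 8 (adjusted p = 0.0258), and the SEC stem 19 higher and 5 lower of 27 (adjusted p = 0.038).

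Collagens were 18 lower and 6 higher of 40 (median -1.22, adjusted p = 0.000346), including COL6A1 (-2.95), COL18A1 (-2.29) and COL4A2 (-2.15), with COL7A1 (1.67) an exception. Fibroblast markers, a list that itself holds collagens, had a median of -1.86 with 6 lower and 1 higher of 11 (adjusted p = 0.33, and 0.00528 with fold changes in place of z), including POSTN (-3.97) and PDGFRA (-1.91). Clustered protocadherins of the beta group were lower in 15 of 16 members (median -3.10, adjusted p = 0.002), including PCDHB2 (-3.60), and tetraspanins in 13 of 21 (adjusted p = 0.0412). The IGSF stem (1 higher and 4 lower of 11) and the sulfotransferase stem CHST (2 higher and 7 lower of 14) also passed toward lower values (adjusted p = 0.0442 for each). Families that did not pass included the integrin stems ITGA (adjusted p = 0.761) and ITGB (0.698), CDH (0.220), PCDHGA (0.574), PCDHA (0.677) and ADAMTS (0.835). PCDHGA was nonetheless 0 higher and 7 lower of 12 (median -2.24), and PCDHA 0 higher and 6 lower of 12 (median -1.09). Lower values were thus not particular to the beta group. All 10 pregnancy-specific glycoprotein genes were higher, with a median of 6.20 (adjusted p = 0.0468), from PSG3 (5.43) to PSG8 (8.89). The PSG and PCDHB genes are neighbours with similar sequences, so their members are not independent and reads can be split between them.

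The immediate early genes, whose fold changes had been seen beforehand, stood apart from lists matched on transcript length and GC content. Their median of 2.71 lay above all 10000 medians of random lists matched on transcript length and GC content (percentile 100.00). The median at the percentile set in advance as the bound was 0.64. Lists of like transcript length and GC content thus did not reach 2.71. The percentile was also 100.00 among random lists without matching, so matching had little room to change it. Genomic span was not matched. The list median was 2.65 above the median of all genes (0.06). A shift of all genes moves both medians alike and leaves this difference unchanged, so it does not account for it. That holds by construction and is not the outcome of a test. The comparison with matched lists was made for all 33 lists. Among lists that passed cameraPR, the medians for p53 (percentile 54.32), PERK-ATF4 (93.92) and fatty acid synthesis (6.15) were not extreme. Among lists that did not pass, those for interferon (0.02), fibroblast (0.01), neuroendocrine (99.96), replication-dependent histone (98.19) and cholesterol synthesis genes (2.14) were. Over all tested genes the rank correlation of fold change was -0.11 with transcript length and -0.05 with GC content, across genes, which are not independent replicates. With genomic span it was -0.08 (15955 genes). A difference in handling at harvest, which can induce immediate early genes within minutes, was not tested and stays open. No biological explanation was tested for the immediate early genes.

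Few genes of the major histocompatibility region carried an adjusted p. Of 176 protein-coding genes that GENCODE 29 places in this region of chromosome 6, 17 did (9.66%), against 15906 of 19599 elsewhere (81.16%). Most of the region's genes were missing from the authors' values altogether: 30 of the 176 were listed, against 16859 of the 19599 elsewhere. Lack of expression is unlikely as the whole reason, since only 3 of 18 widely expressed genes of the region were listed at all, each with an adjusted p (16.67%). Why the others were missing was not tested. Reads shared with alternate copies of the region in the reference are a candidate explanation: 2 other regions known to have such copies also fell short, the leukocyte receptor complex on chromosome 19 with 7 of 41 genes (odds ratio 0.048, Fisher's exact p = 1.39e-18, two-sided) and 17q21.31 with 6 of 15 (odds ratio 0.155, Fisher's exact p = 0.000498, two-sided). Genes of the leukocyte receptor complex are largely immune, so low expression remains open there, and whether the alignment used alternate sequences is not given in the sources used here.

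CYP1A1 (4.98), CYP1B1 (3.13), TIPARP (3.55) and AHR itself (3.79) were higher in libraries D to F, and a difference in AHR activity between the 2 sets (AHR is the aryl hydrocarbon receptor) may be a hypothesis for this. Of 4 further targets chosen before their values were looked at, 2 were higher, AHRR (3.12) and CYP1A2 (2.91), while ALDH3A1 was not called (log2 fold change 0.00 in the authors' deposited table) and UGT1A6 had no adjusted p. The criterion of 3 set in advance was not met, nor was the one that would have counted against it, so the test leaves the hypothesis open.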
